A study of Ovis aries with 24 samples.

How the data were processed

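Gene counts of 12 liver and 12 PVWM libraries were taken as the authors supplied them, as whole-number counts per gene. Per the submitters' processing notes the reads were aligned with Bowtie2 and counted with featureCounts, and edgeR was used on the counts. The versions, the settings and the genome build were not given in the sources used here, and the reads were not used here. Per the labels, total RNA was extracted with Trizol and libraries were made by poly-A selection. Groups, gestational ages, sexes and animal numbers were read from the labels, and no column of the tables was without a sample. Sex was not given for liver animal 060, which is labelled female for PVWM, or for PVWM animal 061.

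Each table held 27716 entries, of which 15015 were symbols found in the gene reference supplied, 1049 were other symbols and 11121 were numeric locus or Ensembl identifiers. Another 508 locus identifiers were named through the reference, including that of CLDN5. Dates stood in place of 23 gene symbols, as happens when symbols pass through spreadsheet software, and held 0.092 to 0.282% of the counts of a library. They were kept under the names given. The symbols HP and CYP7A1, chosen for liver before the data were examined, were not in the table.

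Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Within each tissue, genes were kept by edgeR filterByExpr (16824 in liver, 18616 in PVWM), scaled by trimmed mean of M values and fitted with the 3 groups in one robust quasi-likelihood model. The common biological coefficient of variation was 0.304 in liver and 0.197 in PVWM, with median prior degrees of freedom of 3.92 and 3.87. The 3 contrasts were budesonide against surfactant, surfactant against unventilated and budesonide against unventilated. A gene was called at Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that contrast. CPM are means of library values after scaling, and library log2 values used a prior count of 2. Median-ratio scaling in place of the trimmed mean moved the median log2 change by 0.032 at most. Standard errors were calculated from the edgeR test, as the absolute log2 change divided by the square root of the quasi-likelihood F. The CPM fold of a gene with no counts in a group was bounded below by assigning 3 counts to that group.

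The difference between tissues was tested by edgeR in 1 fit of all 24 libraries with 6 groups, as the liver change minus the PVWM change, over 20010 genes. Libraries of liver and PVWM with the same animal number were taken as the same animal. After removal of group means, the 11 same-animal pairs had correlations of 0.079 to 0.198 (median 0.123, with 6 over 0.1) against a median of -0.032 for different animals. A replicate block for the animal was therefore an alternative fit.

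Gene lists, 30 for liver and 32 for PVWM, were written before the data were examined and cover hormone and immune responses, metabolism, stress responses, and cell types of each tissue. They were compiled from general knowledge and are not a published collection. A list was tested by limma camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a tissue and contrast, and again with the correlation estimated from the data and by fry. The number of members called is also given after adjustment over the list alone. Sequencing depth varied little between groups: liver totals were 16.4 to 19.4 M for unventilated, 17.6 to 23.2 M for surfactant and 16.1 to 18.0 M for budesonide animals, and PVWM totals 15.7 to 16.1, 14.9 to 16.4 and 16.0 to 17.5 M. Between 20139 and 20861 genes were detected per liver library and between 21672 and 22356 per PVWM library. The 10 most abundant genes held 26.1 to 30.1% of counts in liver, led by AHSG, and 2.58 to 3.34% in PVWM.

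Candidates for naming followed a rule. For each contrast they were up to 8 called genes higher and 8 lower with the largest log2 change, a mean of at least 1 CPM, non-overlapping CPM ranges, a symbol, and no role in X inactivation or place on the Y chromosome. Up to 3 called members with the smallest adjusted p were added per list. Before the data were examined, 11 genes for each tissue, 6 more for liver and 6 more for PVWM were set to be reported whatever their result in the contrasts of budesonide against surfactant and surfactant against unventilated. For each tissue difference the 4 genes with the smallest p in each direction were taken. The text names mainly those whose calls held without any single library, plus the genes set beforehand. Some genes that met the rule are not reported here. Across the named results 164 were called, of which 124 stayed past the threshold under every alternative, 40 lost the call under at least 1 and 0 reversed. Another 32 were not called, of which 11 gained a call under at least 1 alternative.

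The calls were tested on simulated data, in which libraries of the observed dispersion held 200 changed genes. At 1.5-, 2- and 4-fold edgeR recovered 0, 28.4 and 77.3% for liver budesonide against surfactant, 3, 22.4 and 89.4% for liver surfactant against unventilated, and 6, 22.4 and 80.3% for liver budesonide against unventilated. In PVWM the recoveries were 31.3, 56.7 and 89.4%, 29.9, 70.1 and 86.4%, and 37.3, 68.7 and 92.4% in the same order. For the tissue differences they were 0, 20.9 and 56.1% and 1.5, 17.9 and 48.5%. The false calls by edgeR were 1, 7 and 3 in liver, 5, 4 and 5 in PVWM and 0 and 0 for the tissue differences, and by DESeq2 24 to 41 per contrast of groups. A list of 19 genes moved by 1.5-fold was called by camera in all 6 simulations, and 0 other lists were. With an estimated correlation it was also called in all 6, and by fry in all but liver budesonide against surfactant (fry adjusted p = 0.0853). The simulated genes varied independently of each other, so these simulations could not show false list calls from genes that vary together.

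Alternatives were fixed before the data were examined: DESeq2, median-ratio scaling, no count filter, a filter of 1 CPM in at least 4 libraries, a fit of the 2 groups compared only, limma voom with quality weights, sex as a covariate (leaving out the library without a sex), gestational age as a covariate, a 2-fold minimum change, and each replicate left out. Tissue differences were refitted with median-ratio scaling, without the filter, with a replicate block, by limma voom with duplicateCorrelation, and with each animal left out. Erythroid and myelin scores as covariates were chosen after results were seen. Group labels were also rearranged in all 35 divisions of 8 animals into groups of 4. For the tissue difference between surfactant and unventilated animals, liver animal 059 and PVWM animal 061, which are different animals, were moved together as 1. Overlap and opposed calls were compared with the product of the list sizes over the number of genes and, for opposed calls, with divided surfactant libraries, and the covariance of the log2 changes also with simulations.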

Results

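Messenger RNA was measured by RNA sequencing in the liver and in the periventricular white matter (PVWM), the brain tissue beside the lateral ventricles, of preterm lambs. The lambs formed 3 groups with 4 animals per tissue. One group was not ventilated. The surfactant group was ventilated and received intratracheal poractant alfa, a porcine lung surfactant, at 2.5 mL/kg. The budesonide group was ventilated and received the same surfactant with budesonide, a synthetic glucocorticoid, at 0.25 mg/kg. The design asks what ventilation with surfactant changed in organs other than the lung, and what budesonide added to that.

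Within each tissue every library came from a separate animal, and 11 of the 13 animals gave both tissues. Total counts ranged from 16.1 to 23.2 M (1e6) per library in liver and from 14.9 to 17.5 M in PVWM. Unventilated lambs were 127 or 128 days of gestation, with 2 labelled males in each tissue. Ventilated lambs were 126 days, except 1 animal of 127 days in each ventilated group, and each ventilated group held 1 male and 3 females. Gestational age was therefore nearly confounded with ventilation. In each ventilated group the male was also the animal of 127 days, 007 with surfactant and 054 with budesonide. Sex and age thus coincided within the ventilated groups, and fits with either covariate could not separate them there. Levels are given as counts per M (CPM), mean ± SD over 4 animals, and changes as log2 differences ± SE with edgeR adjusted p, the quasi-likelihood p after Benjamini-Hochberg adjustment over all genes tested. The CPM ranges of the groups compared did not overlap for any called gene named here, except TAT, G6PC, CXCL8 and SOCS3 in liver between the ventilated groups and SOCS3 in PVWM between surfactant and no ventilation.

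Inflammatory, acute phase and immediate early genes rose in the livers of ventilated, surfactant-treated lambs compared with unventilated lambs. IL6, a cytokine that drives hepatic acute phase synthesis, averaged 63.9 ± 74.1 CPM against no counts in unventilated livers, at least 1822-fold higher by a floor of 3 counts over the group (edgeR adjusted p = 0.00822). That mean came from surfactant animals 049 and 051, at 113 and 142 CPM of IL6, while animals 007 and 032 held 0.222 and 0.720 CPM. C-reactive protein (CRP), secreted by hepatocytes in inflammation, was 13.6-fold higher at 3699 ± 2123 against 272 ± 24.5 CPM (log2 3.77 ± 0.39, edgeR adjusted p = 3.15e-05). SOCS3, a feedback inhibitor of cytokine signalling, rose by 5.21 ± 0.48 on the log2 scale (edgeR adjusted p = 1.47e-05). Ceruloplasmin (CP), a copper-carrying acute phase protein, rose by 6.64 ± 0.59 (edgeR adjusted p = 1.26e-05).

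Of the 31 inflammatory and NF-kB genes measured, 29 were higher with surfactant, among them IL1B (log2 3.45, edgeR adjusted p = 0.00422), CXCL8 (8.07, 0.00158), IL1R1 (3.91, 7.19e-06) and SOD2 (4.06, 8.58e-05). The same 29 was the count adjusted over the list alone, and the camera adjusted p was 2.33e-09 (adjusted p = 0.435 with an estimated correlation). Acute phase proteins were higher in 20 of 23 members, also 20 adjusted over the list alone, with STEAP4 (7.16, edgeR adjusted p = 1.29e-05) and ITIH4 (2.94, 7.85e-06) among them (camera adjusted p = 2.77e-11; adjusted p = 0.164 with an estimated correlation). Immediate early genes, which respond within minutes to cell stimulation, were higher in 27 of 30, or 28 adjusted over the list alone, as for MYC (3.17, edgeR adjusted p = 2.8e-05), KLF6 (2.30, 1.92e-05) and BTG2 (4.18, 5.62e-06). Their camera adjusted p was 6.28e-10 (adjusted p = 0.435 with an estimated correlation). Neutrophil and myeloid markers were higher in 10 of 17 members, 10 adjusted over the list alone, including the chemokine receptor CXCR2 (2.41, edgeR adjusted p = 0.000876; camera adjusted p = 0.000787; adjusted p = 0.487 with an estimated correlation). Endothelial markers were higher in 8 of 18, 9 adjusted over the list alone, led by ANGPT2 (3.57, edgeR adjusted p = 1.47e-05; camera adjusted p = 0.01; adjusted p = 0.435 with an estimated correlation). Interferon-stimulated genes went both ways, 4 higher, as for IRF1 (2.21, edgeR adjusted p = 0.00131), and 7 lower, as for DHX58 (-1.11, 0.00562), of 41 members (4 and 6 adjusted over the list alone; camera adjusted p = 0.421).

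Most of the genes listed as responding to glucocorticoids were higher in the surfactant livers, although that group received no budesonide. Whether any ewe received antenatal steroids, and whether the groups were contemporaries or were sequenced together, was not given in the sources used here. Of 30 members 20 were higher and 2 lower, 21 and 3 adjusted over the list alone (camera adjusted p = 9.48e-06; adjusted p = 0.152 with an estimated correlation). PDK4, a kinase that restrains pyruvate oxidation, was at 3743 ± 1877 against 52.0 ± 11.2 CPM (log2 6.17 ± 0.38, edgeR adjusted p = 1.29e-06). IGFBP1 (3.08, edgeR adjusted p = 3.67e-06), BCL6 (3.87, 1.41e-05), ZBTB16 (3.44, 7.79e-05), DUSP1 (2.24, 0.0031) and FKBP5, a co-chaperone of the glucocorticoid receptor (1.69 ± 0.33, 0.00181), also rose. PER1 (0.67, edgeR adjusted p = 0.0762) and TSC22D3 (-0.44, 0.384) did not pass. PER1 passed without unventilated animal 057 (edgeR adjusted p = 0.0423), and TSC22D3 was lower without surfactant animal 007 (0.049).

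Metabolic genes of the liver moved in several directions. Among gluconeogenic and amino acid breakdown genes 9 were higher and 7 lower of 27 (10 and 7 adjusted over the list alone; camera adjusted p = 0.421). PCK1, which catalyses an early committed step of gluconeogenesis, was at 651 ± 161 against 26.5 ± 13.4 CPM (log2 4.62 ± 0.48, edgeR adjusted p = 3.36e-05), and SDS (6.86, 2.1e-05) and PC (3.04, 1.99e-05) rose too, while tyrosine aminotransferase (TAT) fell by 2.62 ± 0.53 on the log2 scale (0.00218). Sterol biosynthesis genes were lower in 18 of 23 members and higher in 1, PMVK (log2 2.69, edgeR adjusted p = 2.46e-05), with the same counts adjusted over the list alone (camera adjusted p = 3.77e-07; adjusted p = 0.253 with an estimated correlation). NSDHL fell from 48.6 ± 7.91 to 13 ± 2.44 CPM (log2 -1.90, edgeR adjusted p = 1.26e-05) and DHCR7 fell by 2.43 on the log2 scale (5.67e-05). Bile acid and drug metabolism genes were lower in 10 of 17 and higher in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000592; adjusted p = 0.435 with an estimated correlation), as for the xenobiotic receptor NR1I2 (-3.37, edgeR adjusted p = 0.000183) and ALDH1A1 (-2.27, 6.09e-06). Triglyceride synthesis genes DGAT2 (-3.36, edgeR adjusted p = 3.34e-05) and GPAM (-2.88, 0.00029) fell, in a fatty acid synthesis list with 9 lower and 3 higher of 16, the same adjusted over the list alone (camera adjusted p = 0.0623).

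Oxidative phosphorylation genes were lower in 10 of 22 members and higher in 1, also adjusted over the list alone, as for SDHC (log2 -1.34, edgeR adjusted p = 4.51e-05) and NDUFS1 (-1.13, 0.000201; camera adjusted p = 0.003; adjusted p = 0.435 with an estimated correlation). Hypoxia and glycolysis genes were higher in 14 and lower in 1 of 30 (16 and 1 adjusted over the list alone), with LDHA at 2.46 (edgeR adjusted p = 0.000231; camera adjusted p = 0.00396; adjusted p = 0.697 with an estimated correlation). Unfolded protein response genes were higher in 12 and lower in 2 of 26, the same adjusted over the list alone, with XBP1 at 2.06 (edgeR adjusted p = 8.28e-05; camera adjusted p = 0.00591; adjusted p = 0.59 with an estimated correlation). Ribosomal protein genes were higher in 37 of 43, 39 adjusted over the list alone, with a median log2 of 0.67 (camera adjusted p = 2.21e-10; adjusted p = 0.435 with an estimated correlation). Their counts, such as those of RPL6 (19.2 ± 4.19 against 7.68 ± 0.275 CPM, edgeR adjusted p = 0.000156), may be uncertain, since ribosomal genes share sequence with pseudogene copies. This was not tested.

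Across all genes the surfactant and unventilated livers differed in 6911 of 16824 tested, 3629 higher and 3282 lower with surfactant. The largest differences by fold included the transporter SLCO4A1 (477 ± 327 against 0.502 ± 0.365 CPM, log2 9.84, edgeR adjusted p = 6.61e-06), CH25H, which makes 25-hydroxycholesterol (9.42, 0.000698), and the sodium channel subunit SCNN1G, with no counts in unventilated livers (at least 1086-fold higher, 0.00447). Surfactant animal 007 held 31.0 CPM of CH25H against 1003 to 1510.0 CPM in the others of its group. TUBB4A (-3.99, edgeR adjusted p = 0.000225), PALMD (-4.21, 5.18e-05) and the nuclear receptor NR0B2 (-4.19, 0.00114) fell. Heat shock gene HSPA1A (1.09, edgeR adjusted p = 0.412) and cold-inducible CIRBP (-0.34, 0.25) were not called, although CIRBP was lower without animal 007 (0.045). With gestational age as a covariate the count fell to 1398, and IL6, IL1B, CXCL8, CXCR2, IRF1, DHX58, DUSP1, FKBP5, TAT, NR0B2 and SCNN1G lost their calls (edgeR adjusted p = 0.0537 to 0.603). With age the log2 change of IL1B was 1.69 against 3.45 without, that of DUSP1 0.89 against 2.24 and that of FKBP5 1.27 against 1.69, while TAT (-2.30 against -2.62) and DHX58 (-1.34 against -1.11) kept their size. On the first principal component of the liver libraries, which held 54.6% of the variance, animal 007 lay at 12.9, between the unventilated animals (87.4 to 99.7) and the other ventilated ones (-80.4 to -35.4). Animal 007 was the only male and the only animal of 127 days in the surfactant group, so within that group the age covariate rests on it.

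With budesonide added, interferon-stimulated genes and, on average, inflammatory genes were lower in the liver than with surfactant alone. The antiviral gene MX1 was 7.33-fold lower at 4.11 ± 1.23 against 30.1 ± 15.1 CPM (log2 -2.87 ± 0.43, edgeR adjusted p = 0.0023), and MX2 (-3.25, 0.00218) and the chemokine CXCL10 (-3.20, 0.00351) fell with it. Of 41 interferon-stimulated genes 28 were lower and 1 higher, 35 and 1 adjusted over the list alone (median log2 -1.27; camera adjusted p = 1.16e-13; adjusted p = 0.432 with an estimated correlation). IL1B, a cytokine released by activated myeloid cells, was at 1.82 ± 1.08 against 85.6 ± 85.2 CPM (log2 -5.55 ± 0.88, edgeR adjusted p = 0.00329). The surfactant mean of IL1B likewise joins animals 049 and 051, at 141 and 176 CPM, with animals 007 and 032, at 12.9 and 12.8 CPM. Inflammatory and NF-kB genes were lower in 15 of 31 members, 22 adjusted over the list alone, including IL1A (-4.30, edgeR adjusted p = 0.0086) and IL18 (-1.25, 0.00329; camera adjusted p = 0.000106; adjusted p = 0.694 with an estimated correlation). Neutrophil and myeloid markers were lower in 3 of 17, also adjusted over the list alone, with a median log2 of -0.53 (camera adjusted p = 0.0625), and the inflammatory fall was not separated from a change in these cells. The mean log2 CPM of the inflammatory genes was 6.55 and 6.95 in surfactant animals 049 and 051, but 3.81 and 4.55 in animals 007 and 032, against 3.78 to 4.13 in the budesonide livers, so the fall of this list came mainly from animals 049 and 051. LIF, a cytokine of the IL-6 family (-4.87, edgeR adjusted p = 0.00863), the immune checkpoint ligand CD274 (-4.48, 0.00675) and the scavenger receptor OLR1 (-7.50, 0.00578) were among the largest falls.

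CXCL8 (-4.02, edgeR adjusted p = 0.0406) and SOCS3 (-1.51, 0.0312) were also called lower in the budesonide livers, on less secure ground. The call of CXCL8 ended without budesonide animal 031 (edgeR adjusted p = 0.0831), 048 (0.0989), 050 (0.0937) or 054 (0.0803) or surfactant animal 049 (0.0798) or 051 (0.0895). That of SOCS3 ended without budesonide animal 031 (edgeR adjusted p = 0.0898), 048 (0.0749) or 050 (0.0779) or surfactant animal 032 (0.0522), 049 (0.0915) or 051 (0.0527). IL6 was not called (-6.07 ± 1.84, edgeR adjusted p = 0.0604) but passed without surfactant animal 007 (0.0213) or 032 (0.0446) and by DESeq2 (DESeq2 adjusted p = 0.0113). CXCL8 and SOCS3 were also not called from a fit of the ventilated groups alone (edgeR adjusted p = 0.0988 and 0.0845) or with sex as a covariate (0.0861 and 0.0565). Immediate early genes were lower in 4 of 30 members, as for IER3 (-3.72, edgeR adjusted p = 0.00987), with 16 lower and 1 higher adjusted over the list alone. Their camera adjusted p was 0.0127 (adjusted p = 0.805 with an estimated correlation), and the list call ended without surfactant animal 049 (camera adjusted p = 0.276) or 051 (0.249).

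**Figure D1:**
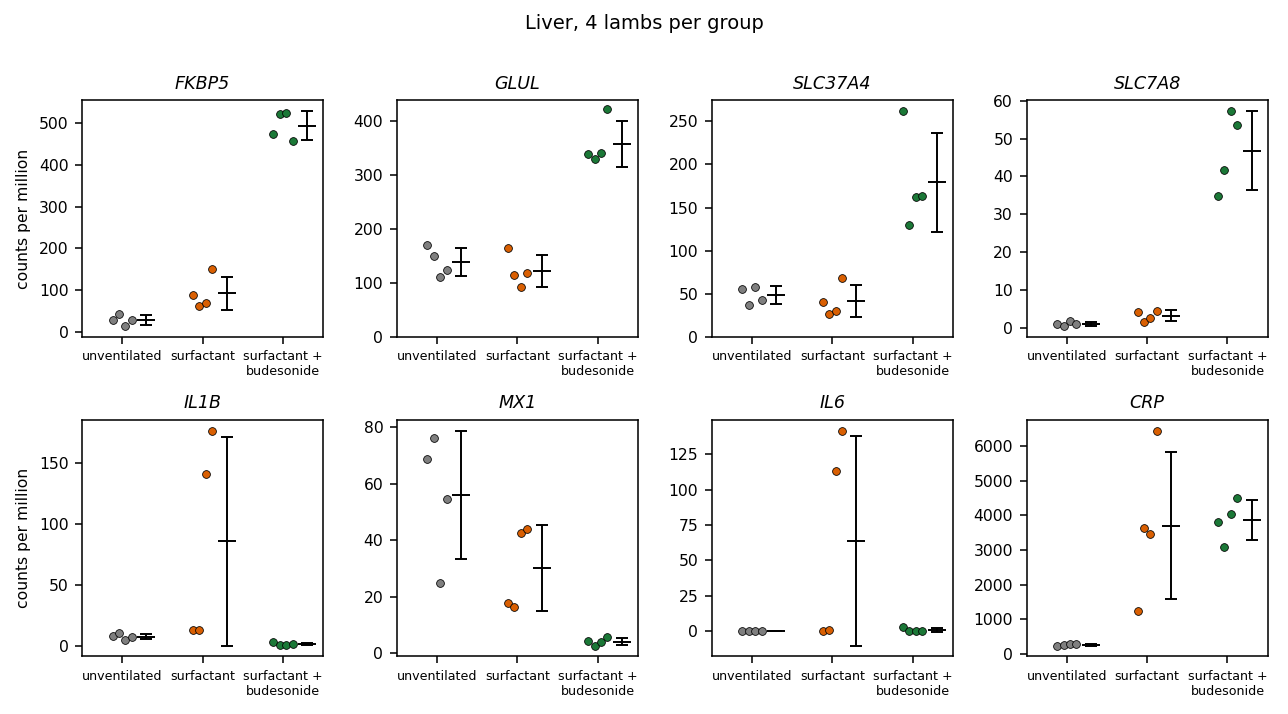
Liver expression of 8 genes in CPM (linear vertical axes) in unventilated, surfactant and surfactant plus budesonide lambs, where each point is 1 animal and the line with whiskers is the mean ± SD over 4 animals. FKBP5 averages 28.6, 92.3 and 495 CPM in that order, and IL6 and IL1B are high in 2 of the 4 surfactant animals.

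Some glucocorticoid-responsive genes rose further with budesonide in the liver. FKBP5 was 5.36-fold higher at 495 ± 34.8 against 92.3 ± 40.3 CPM (log2 2.42 ± 0.34, edgeR adjusted p = 0.00168), and GLUL, glutamine synthetase, was at 358 ± 42.9 against 122 ± 30.2 CPM (1.55, 0.0012). PER1, a clock gene with glucocorticoid response elements, rose by 1.54 (edgeR adjusted p = 0.00692). Of 30 members 8 were higher and 1 lower, 12 and 2 adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.197 with an estimated correlation). TSC22D3, known as GILZ, was called higher (1.63 ± 0.39, edgeR adjusted p = 0.0207), but not without budesonide animal 031 (0.0662) or surfactant animal 032 (0.0538) or 049 (0.0635). TAT was called too (1.80 ± 0.51, edgeR adjusted p = 0.0405), and lost the call without budesonide animal 031 (0.114), 048 (0.0651) or 050 (0.0907) or surfactant animal 032 (0.0936), 049 (0.104) or 051 (0.0692). From a fit of the ventilated groups alone neither TSC22D3 (edgeR adjusted p = 0.0511) nor TAT (0.0932) was called, and TAT was not with sex as a covariate (0.065). DUSP1 (1.49, edgeR adjusted p = 0.0555) and ZBTB16 (1.09, 0.0669) were not called. DUSP1 passed without budesonide animal 054 (edgeR adjusted p = 0.0495) or surfactant animal 049 (0.0151), and ZBTB16 without surfactant animal 051 (0.0333). With sex as a covariate DUSP1 and ZBTB16 passed (edgeR adjusted p = 0.0466 for each), as did DUSP1 with gestational age (0.0287). Both passed by DESeq2 (DESeq2 adjusted p = 0.0133 and 0.0295).

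Some genes of glucose release rose with budesonide, although their list as a whole was not called: SLC37A4, the glucose-6-phosphate transporter, was at 179 ± 57.7 against 41.3 ± 18.6 CPM (log2 2.12, edgeR adjusted p = 0.00201), and G6PC (2.89 ± 0.61, 0.0118) and the aspartate aminotransferase GOT1 (1.69, 0.00689) were higher. PCK1 was not called (0.11 ± 0.41, edgeR adjusted p = 0.882). Of 27 gluconeogenic and amino acid breakdown genes 7 were higher and 2 lower, 10 and 3 adjusted over the list alone. This list had a median log2 of -0.02 but a mean of 0.38, and camera placed it upward with adjusted p = 0.263. CPT1A, which admits fatty acids to mitochondria, rose by 1.47 (edgeR adjusted p = 0.00209), in a list of fatty acid oxidation genes with 3 higher and 1 lower of 24 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.607 with an estimated correlation). Without budesonide animal 031 that list was not called (camera adjusted p = 0.0544). The desaturase FADS1 rose by 1.60 (edgeR adjusted p = 0.00179).

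Some complement, bile acid, growth and endothelial genes were lower with budesonide. Many of these are hepatocyte products, and camera also called the hepatocyte list downward (adjusted p = 0.0088) and the erythroid list upward (0.000895), so a change in cell shares was not separated from a change in expression. Neither of these list calls held with an estimated correlation. Coagulation and complement genes fell in 7 of 33 members, with 21 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.77e-06; adjusted p = 0.6 with an estimated correlation). Complement C3 was at 414 ± 67.4 against 701 ± 55.1 CPM (log2 -0.76, edgeR adjusted p = 0.0117). Acute phase proteins were lower in 2 of 23, C3 and C4BPA (-1.59, edgeR adjusted p = 0.0113), or 4 adjusted over the list alone (camera adjusted p = 0.0156; adjusted p = 0.694 with an estimated correlation), and the list call ended without surfactant animal 051 (camera adjusted p = 0.247). CRP was not called (0.06 ± 0.35, edgeR adjusted p = 0.923). The bile acid receptor NR1H4 (-1.02, edgeR adjusted p = 0.0139) and the canalicular pump ABCC2 (-1.59, 0.0144) fell, in a list with 6 lower of 17 or 11 adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.607 with an estimated correlation). IGF2 (-0.88, edgeR adjusted p = 0.0136) and IGFALS (-1.46, 0.00949) fell among 16 insulin and growth axis genes, of which 4 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.607 with an estimated correlation). That list was not called without budesonide animal 054 (camera adjusted p = 0.0562) or surfactant animal 032 (0.0546). Endothelial markers were lower in 5 of 18, or 12 adjusted over the list alone, as for KDR (-1.03, edgeR adjusted p = 0.00299) and PECAM1 (-0.95, 0.00743; camera adjusted p = 1.67e-05; adjusted p = 0.197 with an estimated correlation).

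In all, 1994 liver genes were called between the ventilated groups, 674 higher and 1320 lower with budesonide. The largest rises included WIPF3 (84.5 ± 10.1 against 5.45 ± 0.735 CPM, log2 3.95 ± 0.16, edgeR adjusted p = 5.34e-08), the amino acid transporter SLC7A8 (46.8 ± 10.4 against 3.30 ± 1.39 CPM, 0.000311), OSR2 (4.62, 0.00179), GHRHR (5.28, 0.00351), FABP4 (4.29, 0.00436) and the clock repressor CRY2 (2.60, 0.0072). HSPA1A (-0.57, edgeR adjusted p = 0.737) and CIRBP (0.49, 0.169) were not called, and CIRBP passed without surfactant animal 007 (0.0387). Erythroid markers had 0 of 14 members called by edgeR and 0 adjusted over the list alone, with 8 higher at unadjusted p under 0.05, 4 higher by DESeq2 and a median log2 of 1.11 (camera adjusted p = 0.000895; adjusted p = 0.694 with an estimated correlation). Hepatocyte genes also had 0 of 18 called by edgeR and 0 adjusted over the list alone, with 6 lower at unadjusted p under 0.05 and 2 lower by DESeq2 (camera adjusted p = 0.0088; adjusted p = 0.694 with an estimated correlation). The number of called genes was 3135 by DESeq2, 884 when the unventilated libraries were left out of the fit, and 1007, 1055 and 1127 without budesonide animal 031, budesonide animal 048 and surfactant animal 049.

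Budesonide livers differed from unventilated livers in 7903 genes, 3918 higher and 3985 lower. Glucocorticoid-responsive genes were higher in 24 and lower in 2 of 30, the same adjusted over the list alone, with FKBP5 at 4.11 ± 0.36 (edgeR adjusted p = 7.94e-06), PDK4 at 6.85 (7.85e-07) and IGFBP1 at 3.85 (7.85e-07). The camera adjusted p was 1.85e-08, and this was the only list in either tissue whose call held with an estimated correlation (adjusted p = 0.0499). Acute phase proteins were higher in 17 of 23, also adjusted over the list alone, as for CP (6.42, edgeR adjusted p = 9.47e-06; camera adjusted p = 6.14e-07; adjusted p = 0.365 with an estimated correlation). Inflammatory genes were higher in 13 and lower in 2 of 31 (15 and 2 adjusted over the list alone; camera adjusted p = 0.00388; adjusted p = 0.717 with an estimated correlation). Interferon-stimulated genes were lower in 30 and higher in 1 of 41 (31 and 2 adjusted over the list alone; camera adjusted p = 3.96e-07; adjusted p = 0.617 with an estimated correlation), with MX1 at -3.77 (edgeR adjusted p = 4.2e-05) and DHX58 at -2.77 (1.85e-05). Sterol genes were lower in 17 and higher in 1 of 23 (17 and 2 adjusted over the list alone; camera adjusted p = 2.48e-06; adjusted p = 0.365 with an estimated correlation), with DHCR7 at -3.18 (edgeR adjusted p = 8.36e-06). Bile acid and drug metabolism genes were lower in 13 and higher in 1 of 17 (14 and 2 adjusted over the list alone; camera adjusted p = 1e-05; adjusted p = 0.365 with an estimated correlation), with NR1I2 at -5.38 (edgeR adjusted p = 1.13e-05).

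Among single genes of that comparison the pentraxin PTX3 (log2 8.46, edgeR adjusted p = 3.33e-05), SLCO4A1 (10.25, 3.69e-06), SDS (8.73, 5.03e-06), BTG2 (4.57, 1.88e-06) and the melanocortin receptor accessory protein MRAP (at least 109-fold higher by the same floor, 0.000255) rose in the livers of the budesonide group. IGFALS (-4.10, edgeR adjusted p = 3.53e-06), the kinase NIM1K (-5.84, 1.63e-06) and KDR (-1.39, 4.15e-05) fell. With gestational age as a covariate the comparison called 2958 genes.

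Of the genes called in both steps in the liver, 577 were opposed, 459 of them higher with surfactant than unventilated and lower again with budesonide, among them IL1B and CXCL8. TAT was among the 118 in the other order, lower with surfactant and higher with budesonide. Another 399 genes moved the same way in both steps. Independent lists of these sizes would share 416.2 opposed and 402.9 same-direction genes. Both steps use the surfactant libraries with opposite sign, and the covariance of the log2 changes over genes was -0.171 against -0.067 in 20 simulations with budesonide unchanged from surfactant. With the surfactant libraries divided so that none served both steps, the covariance averaged -0.043 over 6 divisions (-0.233 to 0.239) with 279.8 opposed genes (92 to 605) and 335 same-direction genes (55 to 712). The divisions varied widely and left open whether budesonide opposed the liver response as a whole. Without budesonide animal 031, 048 or 050 or surfactant animal 049 the opposed count was 271, 335, 379 or 287, without surfactant animal 007 it was 1409, and by DESeq2 it was 981.

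In the PVWM, glucocorticoid-responsive genes rose with ventilation and surfactant. FKBP5 was 8.16-fold higher at 150 ± 30.4 against 18.4 ± 3.44 CPM (log2 3.03 ± 0.17, edgeR adjusted p = 2.45e-06), and PDK4 (3.12, 0.000264), the arrestin-related ARRDC2 (2.32, 4.61e-05) and PER1 (0.72, 0.00295) rose with it. Of 28 members 14 were higher, 22 adjusted over the list alone, with a median log2 of 0.76 (camera adjusted p = 4.23e-21; adjusted p = 0.082 with an estimated correlation). TSC22D3 (0.60, edgeR adjusted p = 0.0267) and ZBTB16 (1.20, 0.0266) were called on narrow margins. TSC22D3 lost its call without surfactant animal 049 (edgeR adjusted p = 0.0515) or 051 (0.0521) or unventilated animal 057 (0.062), 058 (0.0566), 060 (0.0692) or 061 (0.1). ZBTB16 lost its call without surfactant animal 032 (edgeR adjusted p = 0.0564) or 049 (0.0584) or unventilated animal 057 (0.0504) or 061 (0.093). DUSP1 was not called (0.76, edgeR adjusted p = 0.15).

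Some reactive glial and inflammatory genes were higher in the PVWM of the surfactant group. GFAP, the intermediate filament of astrocytes, was 2.73-fold higher at 2695 ± 130 against 987 ± 66.8 CPM (log2 1.45 ± 0.11, edgeR adjusted p = 4.67e-05), and the oncostatin M receptor OSMR rose by 0.92 (0.00848). These were the 2 of 17 reactive glia genes called, with 3 adjusted over the list alone (camera adjusted p = 0.000298; adjusted p = 0.572 with an estimated correlation). Inflammatory genes were higher in 7 of 28 members, or 15 adjusted over the list alone, as for the lipopolysaccharide co-receptor CD14 (2.36, edgeR adjusted p = 0.0022) and NFKBIA (2.08, 0.00298; camera adjusted p = 1.71e-05; adjusted p = 0.581 with an estimated correlation). The chemokine CXCL16 rose by 3.46 (edgeR adjusted p = 4.67e-05) and the urea transporter SLC14A1 by 3.67 (0.00762). IL1B was not called (0.81, edgeR adjusted p = 0.569), and IL6 and CXCL8, with 57 and 199 counts over all PVWM libraries, were too low to test. SOCS3 was called (3.56 ± 0.72, edgeR adjusted p = 0.0224), but not without unventilated animal 057 (0.0527), 058 (0.0728), 060 (0.0995) or 061 (0.079). The p53 and apoptosis list had 3 of 21 higher, 6 adjusted over the list alone, including PMAIP1 (1.67, edgeR adjusted p = 0.000944) and GADD45A (1.48, 0.00174; camera adjusted p = 0.00517; adjusted p = 0.572 with an estimated correlation).

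Lists of neutrophil and macrophage markers were called upward by camera in the PVWM of the surfactant group against no ventilation, although none of their members was called. Neutrophil and myeloid markers had 0 of 10 called by edgeR with surfactant against no ventilation, with 1 higher adjusted over the list alone, 2 higher at unadjusted p under 0.05, 1 higher by DESeq2, a median log2 of 0.56 and a mean of 1.11 (camera adjusted p = 0.0315; adjusted p = 0.572 with an estimated correlation). That list was not called without surfactant animal 051 (camera adjusted p = 0.138) or unventilated animal 058 (0.0728) or 061 (0.0723). Macrophage markers had 0 of 12 called by edgeR, with 2 higher adjusted over the list alone, 4 higher at unadjusted p under 0.05 and 1 higher by DESeq2 (camera adjusted p = 0.0422; adjusted p = 0.745 with an estimated correlation). They were not called without surfactant animal 007 (camera adjusted p = 0.075) or 049 (0.263) or unventilated animal 058 (0.117), 060 (0.0765) or 061 (0.0723). Between budesonide and surfactant the neutrophil and myeloid list moved down, with 0 of 10 called by edgeR, 1 lower adjusted over the list alone, 1 lower at unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.0103; adjusted p = 0.441 with an estimated correlation). This call ended without budesonide animal 048 (camera adjusted p = 0.0511) or surfactant animal 051 (0.0985). The inflammatory change in PVWM was not separated from a change in these cells.

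Some neural progenitor genes and several other single genes were lower in the PVWM of the surfactant group. NPAS4, a neuronal activity-dependent transcription factor, was at 0.248 ± 0.132 against 3.62 ± 0.716 CPM (log2 -3.81, edgeR adjusted p = 0.00181), and EGR4 fell by 1.25 (0.00239) while JUN rose by 0.85 (0.0081). The immediate early list as a whole had 4 higher and 3 lower of 33 (9 and 7 adjusted over the list alone), a median log2 of -0.06, a mean of 0.05 and a downward camera test with adjusted p = 0.521. Neural progenitor and germinal matrix genes were lower in 3 of 18, 4 adjusted over the list alone, as for the matrix protein TNC (-1.07, edgeR adjusted p = 0.00759; camera adjusted p = 0.00878; adjusted p = 0.572 with an estimated correlation), and this list call ended without surfactant animal 051 (camera adjusted p = 0.0611). Ependymal cilia genes, of the cells that line the ventricle, had 0 of 18 called by edgeR and 0 adjusted over the list alone, with 1 lower at unadjusted p under 0.05, 0 by DESeq2 and a median log2 of -0.36 (camera adjusted p = 0.0315; adjusted p = 0.775 with an estimated correlation). They were not called without surfactant animal 049 (camera adjusted p = 0.0807) or 051 (0.838) or unventilated animal 057 (0.494) or 061 (0.0723), and a difference in dissection near the ventricle was not excluded. SALL1, a transcription factor of microglia and progenitors, was the 1 member of 20 microglia genes called lower (-0.86, edgeR adjusted p = 0.000684), also adjusted over the list alone (camera adjusted p = 0.815). SLC38A5 (-1.39, edgeR adjusted p = 0.00531), an amino acid transporter and the 1 of 16 blood-brain barrier genes called, fell, with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.397). The cystine transporter SLC7A11 (-1.44, edgeR adjusted p = 0.00677), PCDH12 (-1.91, 0.00295) and DMP1 (-1.86, 0.00299) fell as well.

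Myelin and mature oligodendrocyte genes had 0 of 21 members called by edgeR between surfactant and unventilated PVWM, and 0 adjusted over the list alone, with 6 higher and 1 lower at unadjusted p under 0.05, 0 by DESeq2 and a median log2 of 1.22 (camera adjusted p = 0.158). MBP was at 1846 ± 2378 against 633 ± 254 CPM (edgeR adjusted p = 0.333), where surfactant animal 051 held 5390.0 CPM. The markers PDGFRA (-0.13, edgeR adjusted p = 0.672), AQP4 (-0.26, 0.33), TTR (-1.06, 0.765) and CLDN5 (0.23, 0.734), and HSPA1A (0.85, 0.398) and CIRBP (0.10, 0.822), were not called. In total 382 of 18616 genes were called, 252 higher and 130 lower. The count was 822 by DESeq2, 174 from a fit of these groups alone, 97 with sex and 15 with gestational age as a covariate, and 197 or 173 without unventilated animal 060 or 061. With age as a covariate FKBP5, PDK4, ARRDC2, GFAP and CXCL16 were still called, and the other named genes of this comparison were not (edgeR adjusted p = 0.0749 to 0.856). Several of the lost changes kept their size: NPAS4 was at -4.07 with age against -3.81 without, SLC14A1 at 4.11 against 3.67, CD14 at 2.47 against 2.36, GADD45A at 1.63 against 1.48, PMAIP1 at 1.63 against 1.67 and SALL1 at -0.81 against -0.86. Others shrank, as JUN from 0.85 to 0.51 and SOCS3 from 3.56 to 2.23. With sex as a covariate the calls of OSMR (0.84, edgeR adjusted p = 0.102), NFKBIA (2.05, 0.0648), JUN (0.82, 0.0881), TNC (-1.11, 0.0502), SLC7A11 (-1.38, 0.0502), TSC22D3 (0.50, 0.253), ZBTB16 (1.45, 0.0634) and SOCS3 (2.99, 0.336) ended, and from a fit of these groups alone those of TSC22D3 (0.0526), ZBTB16 (0.105) and SOCS3 (0.101).

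**Figure D2:**
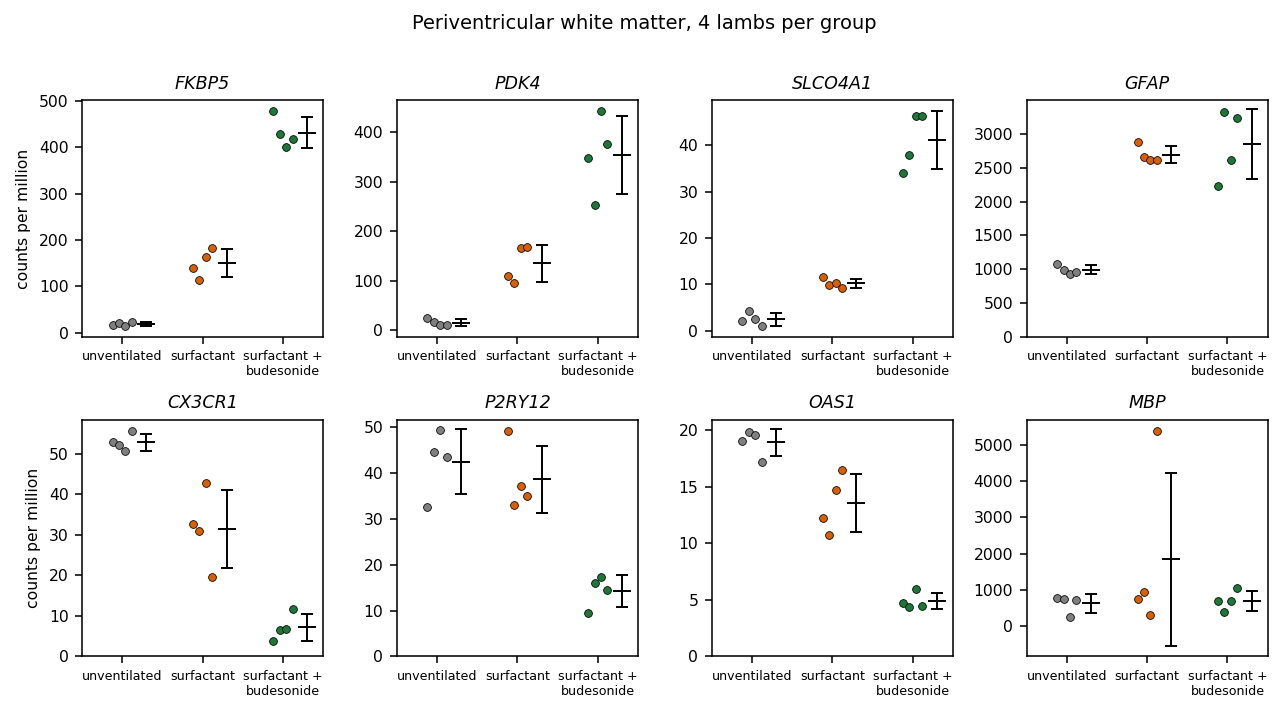
PVWM expression of 8 genes in CPM (linear vertical axes) in unventilated, surfactant and surfactant plus budesonide lambs, where each point is 1 animal and the line with whiskers is the mean ± SD over 4 animals. FKBP5 averages 18.4, 150 and 431 CPM in that order, and CX3CR1 52.8, 31.5 and 7.18 CPM.

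Some glucocorticoid-responsive genes were higher still with budesonide in the PVWM, and some interferon-stimulated and microglial genes were lower. FKBP5 was at 431 ± 33.3 against 150 ± 30.4 CPM (log2 1.52 ± 0.15, edgeR adjusted p = 0.000983), with TXNIP (1.43, 0.00835) and ARRDC2 (1.17, 0.0046) also higher. Of 28 members 7 were higher, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 7.07e-08; adjusted p = 0.323 with an estimated correlation). TSC22D3 was called (0.63, edgeR adjusted p = 0.034), but not without budesonide animal 031 (0.0652), 048 (0.0515), 050 (0.085) or 054 (0.077) or surfactant animal 007 (0.0708), 032 (0.0851) or 049 (0.0739). PER1 (0.46, edgeR adjusted p = 0.0507), ZBTB16 (0.83, 0.146) and DUSP1 (0.25, 0.763) were not called, and PER1 passed without surfactant animal 049 (0.0244).

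The fractalkine receptor CX3CR1, which marks microglia, was 4.39-fold lower at 7.18 ± 3.32 against 31.5 ± 9.55 CPM (log2 -2.13 ± 0.29, edgeR adjusted p = 0.00468). The purinergic receptor P2RY12 was at 14.3 ± 3.43 against 38.6 ± 7.29 CPM (-1.44, edgeR adjusted p = 0.0046) and the growth factor receptor CSF1R, which is also in the macrophage list, fell by 0.98 (0.00165). Of 20 microglia genes 5 were lower, 12 adjusted over the list alone (camera adjusted p = 2.65e-09; adjusted p = 0.25 with an estimated correlation). Macrophage markers were lower in 1 of 12, or 4 adjusted over the list alone (camera adjusted p = 0.0371; adjusted p = 0.619 with an estimated correlation), and that list was not called without budesonide animal 048 (camera adjusted p = 0.0978) or 050 (0.0615) or surfactant animal 049 (0.653). OAS1, an interferon-induced sensor of double-stranded RNA, was at 4.88 ± 0.723 against 13.5 ± 2.55 CPM (-1.47, edgeR adjusted p = 0.000983). Interferon-stimulated genes were lower in 5 of 38, with 17 lower and 2 higher adjusted over the list alone (camera adjusted p = 3.61e-11; adjusted p = 0.0968 with an estimated correlation). Inflammatory genes were lower in 2 of 28, or 13 adjusted over the list alone (camera adjusted p = 7.08e-05; adjusted p = 0.459 with an estimated correlation). IL1B was one of them (-3.49 ± 0.70, edgeR adjusted p = 0.0352) and lost its call without budesonide animal 031 (0.106), 048 (0.0976), 050 (0.107) or 054 (0.0822). The mean log2 CPM of the inflammatory genes was 4.03 and 3.30 in surfactant animals 049 and 051. It was 2.50 and 2.29 in animals 007 and 032, against 2.15 to 2.33 with budesonide, so the fall of this list came mainly from animals 049 and 051. SOCS3 was not called (-2.39, edgeR adjusted p = 0.121), but passed without surfactant animal 007 (0.0157) and by DESeq2 (DESeq2 adjusted p = 0.00729).

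Among other groups in the PVWM, the barrier protein occludin (OCLN) doubled with budesonide (28.5 ± 4.77 against 14.2 ± 1.36 CPM, edgeR adjusted p = 0.00386), and blood-brain barrier genes had 2 of 16 higher, also adjusted over the list alone (camera adjusted p = 0.185). Endothelial markers had 0 of 19 called by edgeR, with 6 lower adjusted over the list alone, 8 lower and 1 higher at unadjusted p under 0.05 and 3 lower by DESeq2 (camera adjusted p = 0.000793; adjusted p = 0.441 with an estimated correlation). Sterol genes were lower in 2 of 23, 3 adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.441 with an estimated correlation). INSIG1, a sterol sensor partner, was one (-0.80, edgeR adjusted p = 0.0173) and was not called without budesonide animal 050 (0.0599). GADD45G (2.03, edgeR adjusted p = 0.00142), SLCO4A1 (41.2 ± 6.22 against 10.2 ± 0.995 CPM, 0.00386) and the kinase SYK (1.60, 0.00775) rose, and OSMR fell by 0.96 (0.0123). From a fit of the ventilated groups alone OSMR (edgeR adjusted p = 0.0586), TXNIP (0.0503), INSIG1 (0.0625), TSC22D3 (0.0999) and IL1B (0.142) were not called, and with sex as a covariate TSC22D3 (0.0668) and IL1B (0.102) were not. Myelin genes had 0 of 21 called by edgeR and 0 adjusted over the list alone, with 2 lower at unadjusted p under 0.05, 0 by DESeq2 and a median log2 of -0.94. Their camera adjusted p was 0.0259 (adjusted p = 0.718 with an estimated correlation), and the list was not called without budesonide animal 048 (camera adjusted p = 0.104) and turned in direction without surfactant animal 051 (0.651).

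MBP (-1.39 ± 0.70, edgeR adjusted p = 0.474), GFAP (0.08, 0.847), PDGFRA (0.28, 0.386), AQP4 (-0.38, 0.173), CLDN5 (-0.18, 0.862), TTR (-1.51, 0.752), CIRBP (0.27, 0.553) and HSPA1A (-1.55, 0.145) were not called between the ventilated groups in PVWM. HSPA1A passed without surfactant animal 007 (edgeR adjusted p = 0.024). The comparison called 182 genes, 110 higher and 72 lower with budesonide, 548 by DESeq2, 69 from a fit of the ventilated groups alone and 80 with sex as a covariate. Without budesonide animal 031, 048, 050 or 054 the count was 78, 73, 66 or 73, and without surfactant animal 032 or 049 it was 115 or 113.

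Against unventilated PVWM, the budesonide group differed in 1501 genes, 810 higher and 691 lower. FKBP5 (log2 4.55 ± 0.18, edgeR adjusted p = 3.16e-08) and PDK4 (4.51, 6.46e-06) led 18 of 28 glucocorticoid-responsive genes that were higher, 21 adjusted over the list alone (camera adjusted p = 9.16e-20; adjusted p = 0.0907 with an estimated correlation). Microglia genes were lower in 8 and higher in 2 of 20 (11 and 2 adjusted over the list alone; camera adjusted p = 4.64e-05; adjusted p = 0.492 with an estimated correlation), with CX3CR1 at 7.18 ± 3.32 against 52.8 ± 2.09 CPM (edgeR adjusted p = 5.57e-05) and SALL1 at -1.22 (8.09e-06). Interferon-stimulated genes were lower in 14 and higher in 1 of 38 (19 and 2 adjusted over the list alone; camera adjusted p = 2.58e-09; adjusted p = 0.0907 with an estimated correlation), with OAS1 at -1.95 (edgeR adjusted p = 7.57e-06). Neural progenitor genes were lower in 6 of 18, also adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.652 with an estimated correlation), with TNC at -1.95 (edgeR adjusted p = 2.75e-05). Immediate early genes were lower in 11 and higher in 3 of 33 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.823 with an estimated correlation), and that list was not called without unventilated animal 058 (camera adjusted p = 0.132). GFAP (1.53, edgeR adjusted p = 6.46e-06), SLC14A1 (5.09, 0.000264) and GADD45G (2.92, 9.81e-06) were higher.

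Vascular genes ENG (log2 -1.60, edgeR adjusted p = 0.0027) and KDR (-0.98, 0.000717) and the precursor-cell transcription factor SOX6 (-0.72, 0.000179) were lower in the budesonide PVWM than in unventilated PVWM. Ependymal cilia genes had 0 of 18 called by edgeR and 0 adjusted over the list alone, with 2 lower at unadjusted p under 0.05, 0 by DESeq2 and a median log2 of -0.48 (camera adjusted p = 0.0293; adjusted p = 0.88 with an estimated correlation). Their list was not called without budesonide animal 031 (camera adjusted p = 0.27) or 050 (0.0665) or unventilated animal 057 (0.29) or 061 (0.05), so the lower progenitor genes here too were not separated from dissection. Endothelial markers were lower in 3 of 19, 4 adjusted over the list alone (camera adjusted p = 0.0365; adjusted p = 0.823 with an estimated correlation). That list was not called without budesonide animal 031 (camera adjusted p = 0.0645) or 050 (0.0525) or unventilated animal 057 (0.0852) or 058 (0.132). The total count was 2422 by limma voom, 668 with sex and 346 with gestational age as a covariate, where KDR lost its call at a similar size (-0.92, edgeR adjusted p = 0.0551), and 998 without budesonide animal 054.

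**Figure D3:**
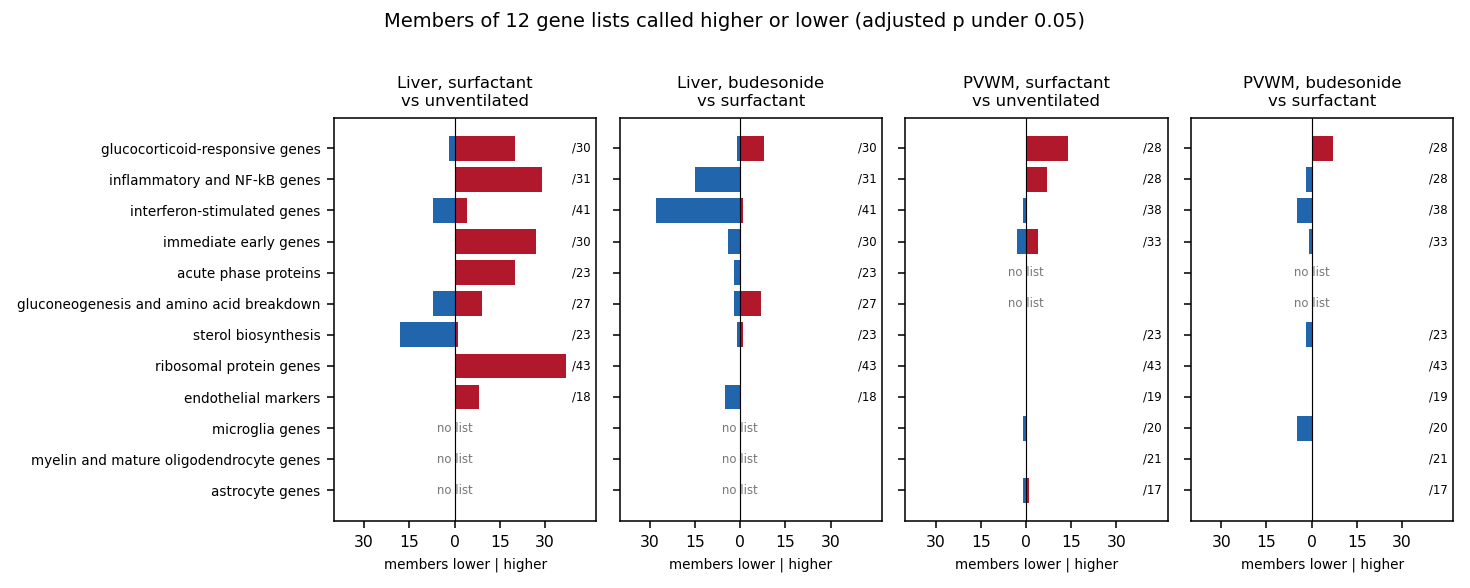
Members of 12 gene lists called by edgeR, with bars to the left for lower and to the right for higher members in each tissue and contrast, and the number measured at the right edge of each panel. Interferon-stimulated genes have 28 members lower and 1 higher with budesonide against surfactant in liver, and 5 lower in PVWM.

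In PVWM, of the genes called in both steps, 46 moved the same way, 41 of them upward, and 7 were opposed. Independent lists of these sizes would give 1.99 and 1.74. The tissues were not tested for a difference in opposed calls. The covariance of the log2 changes was -0.028 against -0.037 in 20 simulations of the same kind. With the surfactant libraries divided, same-direction genes averaged 18.3 (10 to 34) and opposed genes 0.5 (0 to 1), and the covariance averaged 0.028 (0.010 to 0.054). The opposed count was 35 by DESeq2 and 4 without the count filter. Without budesonide animal 031, 048, 050 or 054 it was 1, 2, 1 or 1, without surfactant animal 007, 049 or 051 it was 20, 3 or 4, and without unventilated animal 058, 060 or 061 it was 4, 2 or 2.

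Genes that responded to budesonide overlapped between the tissues. Of 15458 genes tested in both, 33 were higher in both tissues, where 4.36 were expected from 642 and 105 calls (one-sided Fisher's exact p = 1.39e-20), and 31 were lower in both, with 4.9 expected from 1113 and 68 calls (4.15e-18). FKBP5, TSC22D3, SLC37A4, SLC7A8 and SYK were among the shared rises, and IL1B, CXCL10, MX1, OAS1 and P2RY12 among the shared falls. Genes are not independent replicates, and the tissues came from the same ventilated animals. Opposite calls were made for 3 genes, which are named after their values were seen: ASAP3 and SERTAD2 were higher in liver and lower in PVWM, and ARHGAP31 was lower in liver and higher in PVWM. Same-direction genes numbered 64 in all, 187 by DESeq2, and 18, 38, 24, 31, 24 or 29 without animal 031, 032, 048, 049, 050 or 054.

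The difference between the tissues' responses was tested directly over 20010 genes. Between the ventilated groups 683 genes responded differently, 283 more positive and 400 more negative in liver, and 636 of them had the larger change in liver, as did 74.3% of all genes tested. With the animal as a replicate block, since the tissues were paired by animal, 428 genes were called. SLC25A4, a mitochondrial ADP/ATP carrier, rose by 2.76 ± 0.18 in liver but stood at -0.05 ± 0.16 in PVWM (difference 2.81 ± 0.24, edgeR adjusted p = 6.28e-07). ASAP3, a regulator of Arf GTPases, went in opposite directions, 1.54 ± 0.18 in liver and -1.43 ± 0.18 in PVWM (difference 2.97, edgeR adjusted p = 6.28e-07). WIPF3 (3.99, edgeR adjusted p = 2.38e-06) and FABP5 (2.62, 1.68e-05) responded more positively in liver, and PLPP1 (-1.44, 6.88e-05), EHD3 (-1.76, 0.000131), NADK2 (-1.66, 0.000186) and DOCK3 (-1.82, 0.00029) more negatively. FKBP5 was not shown to differ (0.90 ± 0.38, edgeR adjusted p = 0.2), nor was PER1 (1.09 ± 0.31, 0.0513). Leaving out animal 031, 032, 048, 049 or 050 gave 282, 424, 317, 426 or 402 genes, and leaving out 007 gave 1163.

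For surfactant against unventilated animals 5170 genes differed between tissues, 2928 more positive and 2242 more negative in liver, 4994 of them with the larger change in liver, as had 79.1% of all genes tested. STIMATE (difference 3.24, edgeR adjusted p = 1.03e-09), KBTBD11 (4.16, 1.03e-09), AASDH (3.45, 2.58e-09) and WFS1, an endoplasmic reticulum membrane protein (4.37, 2.58e-09), responded more positively in liver. NSDHL (-1.84, edgeR adjusted p = 3.67e-07), SMG6 (-2.45, 3.14e-07), TTBK1 (-4.41, 3.55e-07) and NUDT7 (-4.63, 2.23e-07) responded more negatively. NUDT7 changed by -3.45 ± 0.30 in liver and 1.18 ± 0.31 in PVWM, where it averaged 1.30 with surfactant against 0.568 CPM unventilated. TTBK1 averaged 0.0774 with surfactant against 2.23 CPM unventilated in liver, so both differences rest in part on low levels. FKBP5 (-1.28 ± 0.38, edgeR adjusted p = 0.017) rose more in PVWM, whereas PDK4 (3.14, 3.7e-05), ZBTB16 (2.33, 0.00121) and SLCO4A1 (7.83, 3.67e-07) rose more in liver. GFAP rose in PVWM but not in liver, where it averaged 0.399 against 1.38 CPM (difference -3.18 ± 0.53, edgeR adjusted p = 0.000166). CXCL10 also responded more positively in PVWM (-4.06, edgeR adjusted p = 0.0134).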

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

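Of the explanations weighed here, fewer microglia and faults of single libraries were chosen as tests after results were seen, and the others beforehand. A value was singled out when it stood apart from the other 3 of its group by Dixon's test with a critical ratio found by simulation, which happens by chance in about 1 in 20 groups, and 18 of 384 groups of 4 had one.

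In liver, surfactant animal 007 held 31.0 CPM of CH25H (others 1003 to 1510.0) and 11.2 of CRY2 (2.46 to 2.61), and surfactant animal 051 held 31.2 of MX2 (16.3 to 17.9) and 619 of IGF2 (971 to 1020.0). Budesonide animal 054 held 422 CPM of GLUL (330.0 to 341), 371 of IGF2 (526 to 533), 63.4 of PER1 (98.4 to 101) and 49.0 of ZBTB16 (80.0 to 86.7). IL1B stood at 3.43 in budesonide animal 031 (1.20 to 1.35) and WIPF3 at 99.5 in budesonide animal 050 (77.9 to 81.1). Unventilated animal 057 held 9.35 CPM of IL18 (12 to 12.2) and 58.6 of IL1R1 (40.8 to 43.0), and unventilated animal 059 held 155 of C4BPA (88.5 to 89.4).

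In PVWM, DUSP1 was at 68.2 CPM in budesonide animal 054 (79.9 to 80.5), PER1 at 101 in budesonide animal 048 (114 to 116), OCLN at 19.3 in unventilated animal 058 (15.8 to 16.3) and MBP at 254 in unventilated animal 060 (736 to 793). The total count of PVWM surfactant animal 049 was 14.9 M (16.3 to 16.4). Animal 054, the only male and the oldest animal of the budesonide group, held 5 of the 18 outlying values, and no other animal held more than 2.

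Tissue differences in response were called for 683 genes between budesonide and surfactant and 5170 between surfactant and unventilated animals. As liver minus PVWM, the first were led by SLC25A4 (2.81), ASAP3 (2.97), WIPF3 (3.99) and FABP5 (2.62) and by PLPP1 (-1.44), EHD3 (-1.76), NADK2 (-1.66) and DOCK3 (-1.82). The second were led by STIMATE (3.24), KBTBD11 (4.16), AASDH (3.45) and WFS1 (4.37) and by NUDT7 (-4.63), SMG6 (-2.45), TTBK1 (-4.41) and NSDHL (-1.84). Among genes named in both tissues the second differed for FKBP5 (-1.28), ZBTB16 (2.33), PDK4 (3.14), SLCO4A1 (7.83), CXCL10 (-4.06) and GFAP (-3.18). Liver and white matter differ in cell types and starting levels, and the cause was not tested.

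When the animals were rearranged in 35 divisions, only the real one gave as many called genes as were found, 1 of 35 in every contrast. The real number and the highest other were 1994 and 808, 6911 and 1, and 7903 and 0 in liver, in the order budesonide against surfactant, surfactant against unventilated and budesonide against unventilated. They were 182 and 1, 382 and 126, and 1501 and 1 in PVWM, and 683 and 376, and 5170 and 493 for the tissue differences. A share of 1 in 35 is the lowest that 35 divisions can give, and no adjustment was made for the number of contrasts. Mixed divisions also place treatment differences inside the groups, which can lower their counts. Chance division of the animals was thus made less likely for the numbers of genes, but was not excluded. For the numbers of lists called by camera other divisions often did as well. In liver 13, 14 and 17 lists were equalled or passed in 9, 13 and 7 divisions (highest other 15, 18 and 19), and in PVWM 14, 10 and 10 lists in 8, 16 and 5 divisions (17, 16 and 11).

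Some microglia genes were lower in PVWM with budesonide than with surfactant alone, which could reflect fewer microglia, less expression per cell, or another share of myelin in the dissection. With fewer cells all members would fall alike, but 4 of 20 had a 95% interval above the list median of -0.47, among them AIF1 (0.17), CD68 (-0.02) and IRF8 (0.27). These normal intervals from the SE may be too narrow for groups of this size. A myelin score as covariate left 12 members lower when adjusted over the list alone, with CX3CR1 at -2.18 ± 0.27 (edgeR adjusted p = 0.00469) against -2.13 ± 0.29 (0.00468) without it. Both outcomes speak against these explanations in their simple form. Members read by other macrophages or by microglia in another state may still bear on the list, which was not tested.

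Glucocorticoid-responsive genes were higher in PVWM with surfactant than unventilated, 22 of 28 adjusted over the list alone, in a group that received no budesonide. Sex or gestational age could contribute, since both differed between the groups. With sex as a covariate 16 members were higher (FKBP5 at 3.13 ± 0.20, edgeR adjusted p = 0.000161), and with gestational age 13 were (FKBP5 at 2.92 ± 0.24, 0.000736). Fewer than 11 would have spoken for the explanation and 17 or more against it, so neither test decided. The median log2 of the list was 0.76 without a covariate, 0.74 with sex and 0.61 with age, with median SE of 0.23, 0.28 and 0.33, so the lost calls go with larger errors more than with smaller changes.

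Inflammatory genes varied among the livers of the surfactant group, with mean log2 scores of 3.81, 4.55, 6.55 and 6.95 in animals 007, 032, 049 and 051 and 2.50, 2.29, 4.03 and 3.30 in their PVWM, against 3.78 to 4.13 in the budesonide livers. If single libraries were at fault, liver and PVWM of an animal would not deviate together. Over 11 animals the deviations from the group mean had Pearson r = 0.829 (exact permutation p = 0.23 within groups) and Spearman rho = 0.836 (p = 0.0946) over 3456 rearrangements, the 1 relation tested, and r = 0.98 and rho = 0.733 without animals 007 and 051. That r rests mainly on animals 032 and 049 (liver -0.91 and 1.08, PVWM -0.74 and 1.00), with the others at -0.25 to 0.10 in liver. The group means were not recalculated for it. The correlation did not decide the matter, and it may be that the animals differed in inflammation. Leaving out 1 surfactant animal kept at least 16 members lower with budesonide in liver (without animal 051) of the 22 of 31 lower adjusted over the list alone, but that cannot show that the fall is shared, and by the scores it came mainly from animals 049 and 051.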

How the results depend on the processing

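Erythroid and myelin scores as covariates moved no count of genes by more than 1.5-fold, the measure used here for a moved count.

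Between budesonide and surfactant in liver the 1994 called genes became 3135 by DESeq2, 884 with the 2 groups only, 1229 with a 2-fold minimum, and 1007 (without budesonide animal 031) to 2838 (without surfactant animal 051) as single animals were left out. The low end was shared by budesonide animal 048 (1055) and surfactant animal 049 (1127). Surfactant against unventilated in liver went from 6911 to 1398 with gestational age as a covariate and 3894 with the 2-fold minimum, and single animals gave 5509 to 8109. Budesonide against unventilated in liver went from 7903 to 2958 with age and 4634 with the 2-fold minimum (6654 to 7280.0 by animal). As age and ventilation nearly coincide, these falls do not separate them.

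In PVWM the 182 genes between budesonide and surfactant became 548 by DESeq2, 69 with the 2 groups only, 80 with sex and 78 with the 2-fold minimum, and 66 to 166 without single animals. Fewer were called without each of the animals 031, 048, 050, 054, 032 and 049. Surfactant against unventilated went from 382 to 822 by DESeq2, 174 with the 2 groups only, 97 with sex, 15 with gestational age, 159 with the 2-fold minimum and 173 (without unventilated animal 061) to 501, with 197 without animal 060. Budesonide against unventilated went from 1501 to 2422 by limma voom, 668 with sex, 346 with age, 543 with the 2-fold minimum and 998 (without budesonide animal 054) to 1221 without unventilated animal 058. The sex fit also lost the library without a sex, and the cause was not tested.

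Opposed calls in liver were 577, or 981 by DESeq2 and 271 to 1409 by animal. In PVWM they were 7, or 35 by DESeq2, 4 without the filter and 1 to 20 by animal. The overlap of the tissues, 64 genes, became 187 by DESeq2 and 18 to 74 by animal. Tissue differences between budesonide and surfactant went from 683 to 428 with the replicate block and 282 to 1163 by animal, and between surfactant and unventilated from 5170 to 3755 and 3927 to 6230.0. The 16 genes named for the smallest p kept their calls with the replicate block, and the genes named in both tissues were not refitted with it.

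With an estimated correlation the lists called fell from 13, 14 and 17 in liver to 0, 0 and 1, and from 14, 10 and 10 in PVWM to 0, 0 and 0, with contrasts in the order given above. By fry they were 7, 17 and 18 in liver and 2, 1 and 6 in PVWM. Without single animals they ranged over 12 to 16, 14 to 19 and 15 to 19 in liver and 12 to 18, 5 (without surfactant animal 051; 6 without unventilated animal 061) to 12, and 7 to 12 in PVWM. The myelin list between budesonide and surfactant in PVWM had a camera adjusted p of 4.86e-07 without surfactant animal 049 and 0.651, with its direction reversed, without surfactant animal 051, the animal with high MBP. No other called result was reversed, and some results that were not called, such as TTR and HSPA1A, changed sign between alternatives.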

Other observations

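Of the further liver lists given here, camera called all but the macrophage markers, and no call held with an estimated correlation. The p53 and apoptosis genes were higher in 13 and lower in 1 of 21 with surfactant against no ventilation, the same adjusted over the list alone (camera adjusted p = 0.00173; adjusted p = 0.152 with an estimated correlation). Mesenchymal and matrix genes were higher in 7 of 18 in that contrast, also adjusted over the list alone (camera adjusted p = 0.00251; adjusted p = 0.435 with an estimated correlation). Macrophage markers were 5 higher and 2 lower of 17 there, also adjusted over the list alone (camera adjusted p = 0.245). Proliferation genes had 0 of 34 called by edgeR between the ventilated groups in liver, 0 adjusted over the list alone, 1 higher at unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.00386; adjusted p = 0.805 with an estimated correlation), and the list was not called without budesonide animal 054 (camera adjusted p = 0.0781) or surfactant animal 007 (0.112). Coagulation and complement genes were lower in 13 and higher in 4 of 33 with budesonide against no ventilation, also adjusted over the list alone (camera adjusted p = 0.0192; adjusted p = 0.683 with an estimated correlation), and not called without unventilated animal 059 (camera adjusted p = 0.0865).

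In PVWM between the ventilated groups, heat shock genes had 0 of 19 called by edgeR, 0 adjusted over the list alone, 3 lower at unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.000101; adjusted p = 0.441 with an estimated correlation). Reactive glia genes were lower in 2 of 17, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0371; adjusted p = 0.546 with an estimated correlation), and not called without budesonide animal 050 (camera adjusted p = 0.107) or 054 (0.0728) or surfactant animal 049 (0.284). Immediate early genes were lower in 1 of 33, or 7 adjusted over the list alone (camera adjusted p = 0.000833; adjusted p = 0.459 with an estimated correlation).

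The glucocorticoid-responsive list of the liver, budesonide against unventilated, lay at the threshold with an estimated correlation (adjusted p = 0.0499). Lists built from single cell types in unventilated preterm lambs, measured cortisol, and animals matched for gestational age would separate readings that these libraries leave open. Staining of microglia in the same white matter could tell fewer cells from lower expression, on which the 4 of 20 members above the list median bear only in part.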
